A study of Homo sapiens with 24 samples.

How the data were processed

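RNA of 24 cultures of the human embryonic stem cell lines H1, H7 and H9 was measured, 1 array per culture, on Agilent 1-colour (Cy3) whole human genome arrays. The arrays form 8 groups of 3, with each line once per group. RSeT cultures (a medium for naive-like cells) were taken at passage 4 or 10 and primed cultures (standard stem cell medium) in batch 1 or 2, each at 20% oxygen (normoxia) or 3% oxygen (hypoxia). The labels do not show separate cultures beyond the line, so the 3 lines are the replicates and the line is a block in every main fit. Beyond the line term the fit treats arrays of 1 line in different groups as independent. Its standard errors and p values can therefore understate how far an effect varies between lines. Per the labels, RSeT cells were grown on mouse embryonic fibroblast feeders.

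Per the file headers, the deposited scanner files hold spot intensities from Agilent Feature Extraction 12.0.1.1, while the labels name version 9.1. Per the file headers, the processed intensity was background-subtracted and detrended, with low values replaced by a surrogate, and was not scaled between arrays. The files also hold the mean and local background intensity of each spot as deposited, and marks for spots well above background, saturated or not uniform. The deposited series matrix holds log2 values whose scaling the authors do not state. Set against the scanner files, each of its columns correlated best with its own array (Pearson r 0.974 to 0.983 across probes, against at most 0.971 for any other array). The matrix values behave as log2 of the processed intensity less 39.0 to 54.4, with 29.4% to 44.8% of values per array at exactly 1. Its column medians of 4.46 to 7.86 show no scaling between arrays. Why its lowest values are negative (-10.97 to -5.06) stays unknown.

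Each array has 43376 spots for 41000 probes after control spots were left out. Spots marked as outliers (0.0945% to 0.56% per array) were left out and replicate spots averaged. No spot was saturated and no processed intensity was 0 or below. Probes were named through RefSeq accessions (28954), current symbols (2455) or older symbols (228), and 9363 kept the name in the file. The names of 1779 probes differed between the 2 design files. XIST, TSIX and genes of chromosome Y (112 probes) were left out throughout. Probe positions are from the files (hg19).

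The value analysed is log2 of the processed intensity minus log2 of the array's 75th percentile. A probe was tested if it was well above background on all 3 arrays of at least 1 group, and the probe with the highest mean stood for its gene, which left 23313 genes. No named gene had another tested probe called in the opposite direction. Group means and the line were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p values were adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene is called at an adjusted p under 0.05. Of the comparisons, 9 were contrasts of the 8 group means and 2 were moderated F tests of whether the medium or oxygen effect differs between lines. Errors are standard errors of the fit (SE). A gene not well above background on every array of a side has only a bound: the bright side's mean against the mean, per array, of the higher of the lowest signal well above background and the gene's own signal. The precision is limited by the number of arrays.

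Named genes came from a fixed rule: the 10 largest called differences in each direction with the same sign in all 3 lines, the up to 4 members of each list with the smallest p, and 20 pluripotency and hypoxia genes. The 29 gene lists cover pluripotency states, cell types, metabolism, signalling, stress and other programmes, and fibroblast markers for the feeder cells. A list was tested with limma's camera at a preset correlation of 0.01 (adjusted over lists within a comparison). Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives. These comparisons, tests, lists, rules and most alternatives were chosen before the data were examined.

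Alternatives were quantile normalization, normexp background correction (offset 50), a signal floor, the series matrix values, other filters on dim probes, the mean of probes, no replicate block, the slide as a block, trend and robust eBayes, only the compared arrays, stricter calls (adjusted p under 0.01, or 2-fold as well), each scan alone, and leaving out each array or line. A scan alone means that the contrast was limited to the groups of 1 scan, while the line terms and the spread came from all arrays. Only the line F tests were refitted on the arrays of 1 scan. Leaving out a pair of H9 arrays, the scan alone for the interactions and a common signal floor were chosen after seeing the data. The common floor raises every scaled signal to the highest, over the arrays, of the lowest signal well above background (-4.97 on the log2 scale). The fit was tested on simulated data. With no effect it called 0 genes in any comparison. With 200 changed genes it recovered 95.5% of 4-fold and 76.1% of 2-fold changes between the media, but 80.3% and 26.9% for the oxygen by medium interaction. Splits of the samples, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served the remaining steps. The adjusted p values in the text are from limma. The files name 6 slides of 4 arrays. Each slide holds 1 line at 1 scan, with both media at both oxygen levels. Passage 4 and batch 1 were on scan 1, and passage 10 and batch 2 on scan 2. The slide as a block leaves the list medians almost unchanged, since each slide holds each side of the medium and oxygen comparisons equally.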

Results

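RNA was measured in 24 cultures of the embryonic stem cell lines H1, H7 and H9, which the study used to ask how cells in RSeT medium resemble naive, formative or primed pluripotency and how oxygen affects them. Each of the 8 groups held 3 arrays, 1 per line: RSeT cells at passage 4 or 10 and primed cells of batch 1 or 2, each at 20% oxygen (normoxia) or 3% oxygen (hypoxia). The 75th percentile of the processed signal was 1499 to 2414 on the normoxia arrays and 609 to 1863 on the hypoxia arrays. Between 63.0% and 84.1% of the probes on an array were well above background, 63.0% to 77.2% on scan 1 and 77.6% to 84.1% on scan 2. Scan 1 held passage 4 and batch 1, and scan 2 held passage 10 and batch 2. Differences below are log2 units of the scaled signal with the standard error of the fit (SE), and n is the number of arrays. The size of a difference is uncertain where a gene was well above background on only some arrays of a side. A common floor, to which every signal was raised, was therefore added after seeing the data. Arrays of 1 line resembled each other after the group means were removed (mean Pearson r 0.292 across genes, which are not independent replicates, and 72 of 84 pairs over 0.1). The mean for different lines was -0.146. With 1 array per line in each group, removing group means ties this value to the former, so it is no separate evidence.

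A pair of H9 arrays stood apart from their labels. On a scale built from the other 2 lines, where primed arrays average 0 and RSeT arrays average 1, the array labelled primed batch 1 hypoxia H9 scored 1.07 and the array labelled RSeT passage 4 hypoxia H9 scored 0.0292. The other 11 primed arrays scored -0.20 to 0.29 and the other 11 RSeT arrays 0.63 to 1.16. On this slide the positions of the hypoxic primed and RSeT arrays were also reversed relative to the other 5 slides. The labels were kept, and each leading count is also given without this pair, an alternative added after seeing the data. This pair bears on every count that uses the hypoxia arrays.

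**Figure D1:**
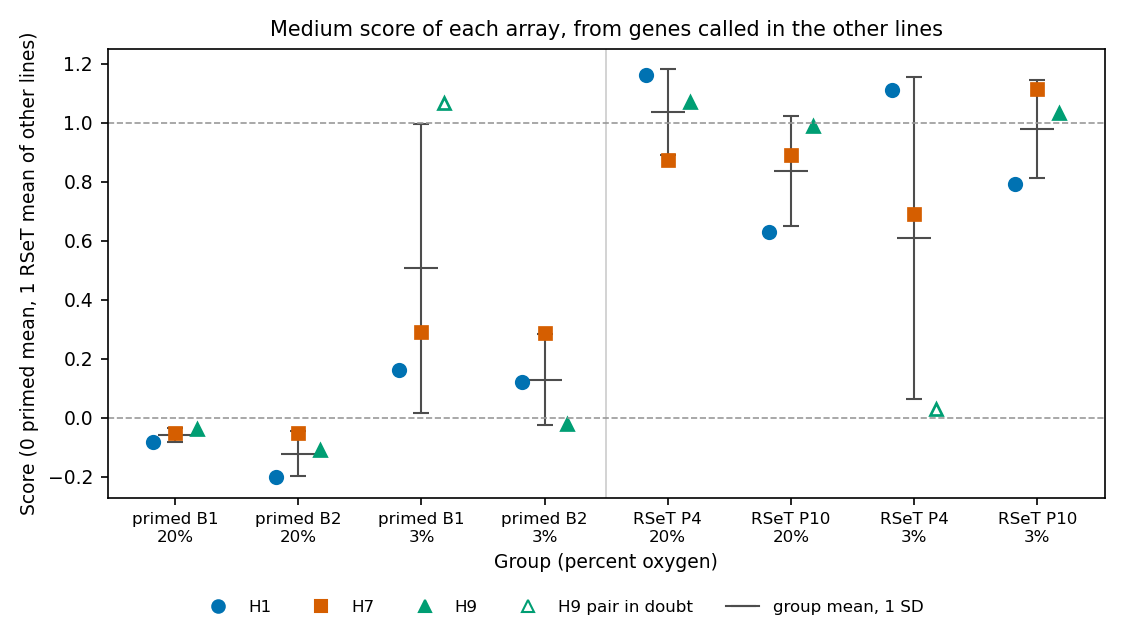
RSeT score of each of the 24 arrays (0 is the mean of primed arrays and 1 the mean of RSeT arrays of the other lines), by group and line. The arrays labelled primed batch 1 hypoxia H9 (1.07) and RSeT passage 4 hypoxia H9 (0.0292) lie with the other medium.

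RSeT medium was set against primed medium over both oxygen levels (n = 12 and 12) to ask which pluripotency state the cells resembled. Genes linked to naive pluripotency rose in RSeT: KLF4, a transcription factor of the naive network (probe at chromosome 9, 110248049 to 110248108, hg19), by 1.36 ± 0.21 (SE; adjusted p = 0.000362), DNMT3L, a cofactor of DNA methyltransferases, by 2.20 ± 0.38, and the surface marker SUSD2 by 1.12 ± 0.19. DPPA5 rose by 2.66 ± 0.57, TFCP2L1 by 0.88 ± 0.17 and DPPA3 by 1.57 ± 0.25, though DPPA3 was well above background on only 6 RSeT and 2 primed arrays. Of 22 measured naive genes 11 were higher and 3 lower (12 and 3 adjusted over the list alone), with a list median of 0.90 (adjusted p = 0.00268 by camera, adjusted p = 0.427 with an estimated correlation). That median was 0.53 within scan 1, 1.00 there without the H9 pair, and 1.44 within scan 2. It was 0.46 with the common floor, where DPPA3 was not called. KLF17, another naive marker, was not among the genes tested.

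Most shared pluripotency genes did not pass the test. POU5F1 (0.08 ± 0.14, adjusted p = 0.702), SOX2 (0.10 ± 0.09, adjusted p = 0.424), NANOG (-0.60 ± 0.25, adjusted p = 0.089) and DNMT3B (-0.06 ± 0.13) did not pass, nor did the primed and formative genes SOX11 (0.41 ± 0.15, adjusted p = 0.0505) and ZIC2 (-1.13 ± 0.44, adjusted p = 0.0637). Without the H9 pair NANOG (-0.93) and ZIC2 (-1.53) were called lower. The list of shared pluripotency genes had 4 higher and 2 lower of 24 (3 and 2 adjusted over the list alone). Their median was -0.08 (adjusted p = 0.931).

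Primed and formative lists leaned lower. These lists share members, OTX2 among them, and both share members with the FGF-ERK response list below, such as DUSP6, MYC and ETV4. OTX2, a factor of formative and primed cells, fell by 1.01 ± 0.26 on the log2 scale, and MYC by 2.23 ± 0.35. Of 24 primed genes 3 were higher and 12 lower (4 and 15 adjusted over the list alone). Their median was -0.83 (adjusted p = 0.000236, adjusted p = 0.332 with an estimated correlation), and -0.66 and -0.68 within scans 1 and 2. Of 22 formative genes 2 were higher and 8 lower (3 and 9 adjusted over the list alone). Their median was -0.43 (adjusted p = 0.00113, adjusted p = 0.464 with an estimated correlation), -0.21 in scan 1, -0.54 there without the pair, and -0.58 in scan 2.

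Targets of growth factor signalling fell. DUSP6, a phosphatase induced by ERK (probe at chromosome 12, 89742144 to 89742203), was lower by 4.43 ± 0.71 (adjusted p = 0.000428), the immediate early gene EGR1 by 5.03 ± 0.88 and ETV4 by 1.47 ± 0.28. Of 19 FGF-ERK response genes 0 were higher and 16 lower, the same counts as when adjusted over the list alone. Their median was -1.33 (adjusted p = 8.73e-09, adjusted p = 0.232 with an estimated correlation), -1.05 in scan 1, -1.79 there without the pair, and -1.68 in scan 2. GSC, a member of the primitive streak and mesoderm list, fell by 4.39 ± 0.70. Among activin-NODAL response genes, CER1 fell by 4.40 ± 0.77 (well above background on 1 RSeT and 11 primed arrays, 1.94 with the common floor) and LEFTY1 by 4.29 ± 1.09. Here 10 of 13 were lower and 0 higher, also when adjusted over the list alone. Their median was -1.38 (adjusted p = 2.57e-06, adjusted p = 0.213 with an estimated correlation), and -1.53 and -1.42 within the scans.

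Endoderm and primitive streak lists leaned lower in RSeT. TTR, a transport protein of visceral endoderm and liver, fell by 5.84 ± 0.63 (well above background on 3 RSeT and 10 primed arrays), APOA1 by 4.93 ± 0.42 (5 and 11 arrays), APOA2 by 3.32 ± 0.32 and GATA4, an endoderm transcription factor, by 2.68 ± 0.30 (6 and 11 arrays). Of 23 endoderm genes 14 were lower and 0 higher, also when adjusted over the list alone. The endoderm median was -1.36 (adjusted p = 8.19e-10, adjusted p = 0.115 with an estimated correlation), and -0.66 and -1.60 within the scans. With 2 endoderm members that were not well above background on any array of a side set at their bound, this median was -0.93. EOMES, a primitive streak factor, fell by 5.11 ± 0.83 (2 and 11 arrays) and MIXL1 by 1.85 ± 0.19 (10 and 12 arrays). Among 18 primitive streak and mesoderm genes 1 was higher and 8 lower, also when adjusted over the list alone. Their median was -0.19 (adjusted p = 0.00257, adjusted p = 0.213 with an estimated correlation), -0.24 in scan 1, -0.41 there without the pair, and -0.48 in scan 2. Trophectoderm and amnion genes had 1 higher and 4 lower of 21, also when adjusted over the list alone. Their median was -0.27 (adjusted p = 0.0383, adjusted p = 0.361 with an estimated correlation), -0.24 in scan 1, -0.45 there without the pair, and -0.18 in scan 2. That list was not called with the common floor (-0.04, adjusted p = 0.144), nor without the pair (adjusted p = 0.056).

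Fibroblast genes, included because RSeT cells grew on feeder cells, leaned lower in RSeT. TAGLN, a smooth muscle and fibroblast cytoskeletal gene, fell by 3.88 ± 0.37 and the matrix gene LUM by 2.74 ± 0.37 (4 and 9 arrays, 0.81 with the common floor). Of 23 fibroblast genes 2 were higher and 11 lower (3 and 12 adjusted over the list alone). Their median was -0.37 (adjusted p = 0.000236, adjusted p = 0.213 with an estimated correlation), -0.11 in scan 1, -0.05 there without the pair, and -0.51 in scan 2.

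Metabolic genes leaned higher. The glycolytic enzymes GPI (0.64 ± 0.08) and ALDOA (0.50 ± 0.11) rose while HK1 fell by 0.62 ± 0.13, and 11 of 20 glycolysis genes were higher and 1 lower (14 and 1 adjusted over the list alone). Their median was 0.33 (adjusted p = 0.000979, adjusted p = 0.427 with an estimated correlation), and 0.48 and 0.20 within the scans. The respiratory chain genes NDUFV1 (0.77 ± 0.12) and COX5A (0.49 ± 0.08) rose, among 17 higher and 0 lower of 45 oxidative phosphorylation genes (20 and 0 adjusted over the list alone). Their median was 0.24 (adjusted p = 0.000492, adjusted p = 0.427 with an estimated correlation), and 0.19 and 0.30 within the scans. Cholesterol synthesis genes had 6 higher and 1 lower of 25, also when adjusted over the list alone. Their median was 0.29 (adjusted p = 0.0305, adjusted p = 0.514 with an estimated correlation), 0.05 in scan 1, 0.12 there without the pair, and 0.44 in scan 2. Cell cycle genes had 2 higher, PLK1 (0.39 ± 0.07) among them, and 6 lower, CDK1 (-0.38 ± 0.10) among them, of 32 (2 and 5 adjusted over the list alone). Their median was -0.22 (adjusted p = 0.00268, adjusted p = 0.427 with an estimated correlation), and -0.31 and -0.11 within the scans.

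Large rises included the zinc finger gene ZNF560 (4.76 ± 0.46, well above background on 11 RSeT and 2 primed arrays), ZNF300P1 (4.03 ± 0.38, 10 and 1 arrays), CD3G (3.89 ± 0.45, 11 and 5 arrays), CD70 (3.35 ± 0.69, 12 and 11 arrays) and BCL3, a target of STAT3 (2.86 ± 0.36). Large falls included the cardiac myosin gene MYL7 (5.72 ± 0.69 lower, 10 and 12 arrays) and CST1 (5.45 ± 0.57 lower, 5 and 11 arrays). In all, 3633 genes were higher and 2501 lower of 23313 tested, 745 and 717 of them by at least 2-fold. Without the H9 pair 5860 were higher and 4787 lower, and 6074 genes were called with and without it. Scan 1 alone gave 3029 called genes, scan 2 alone 2874 and normexp 3613.

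**Figure D2:**
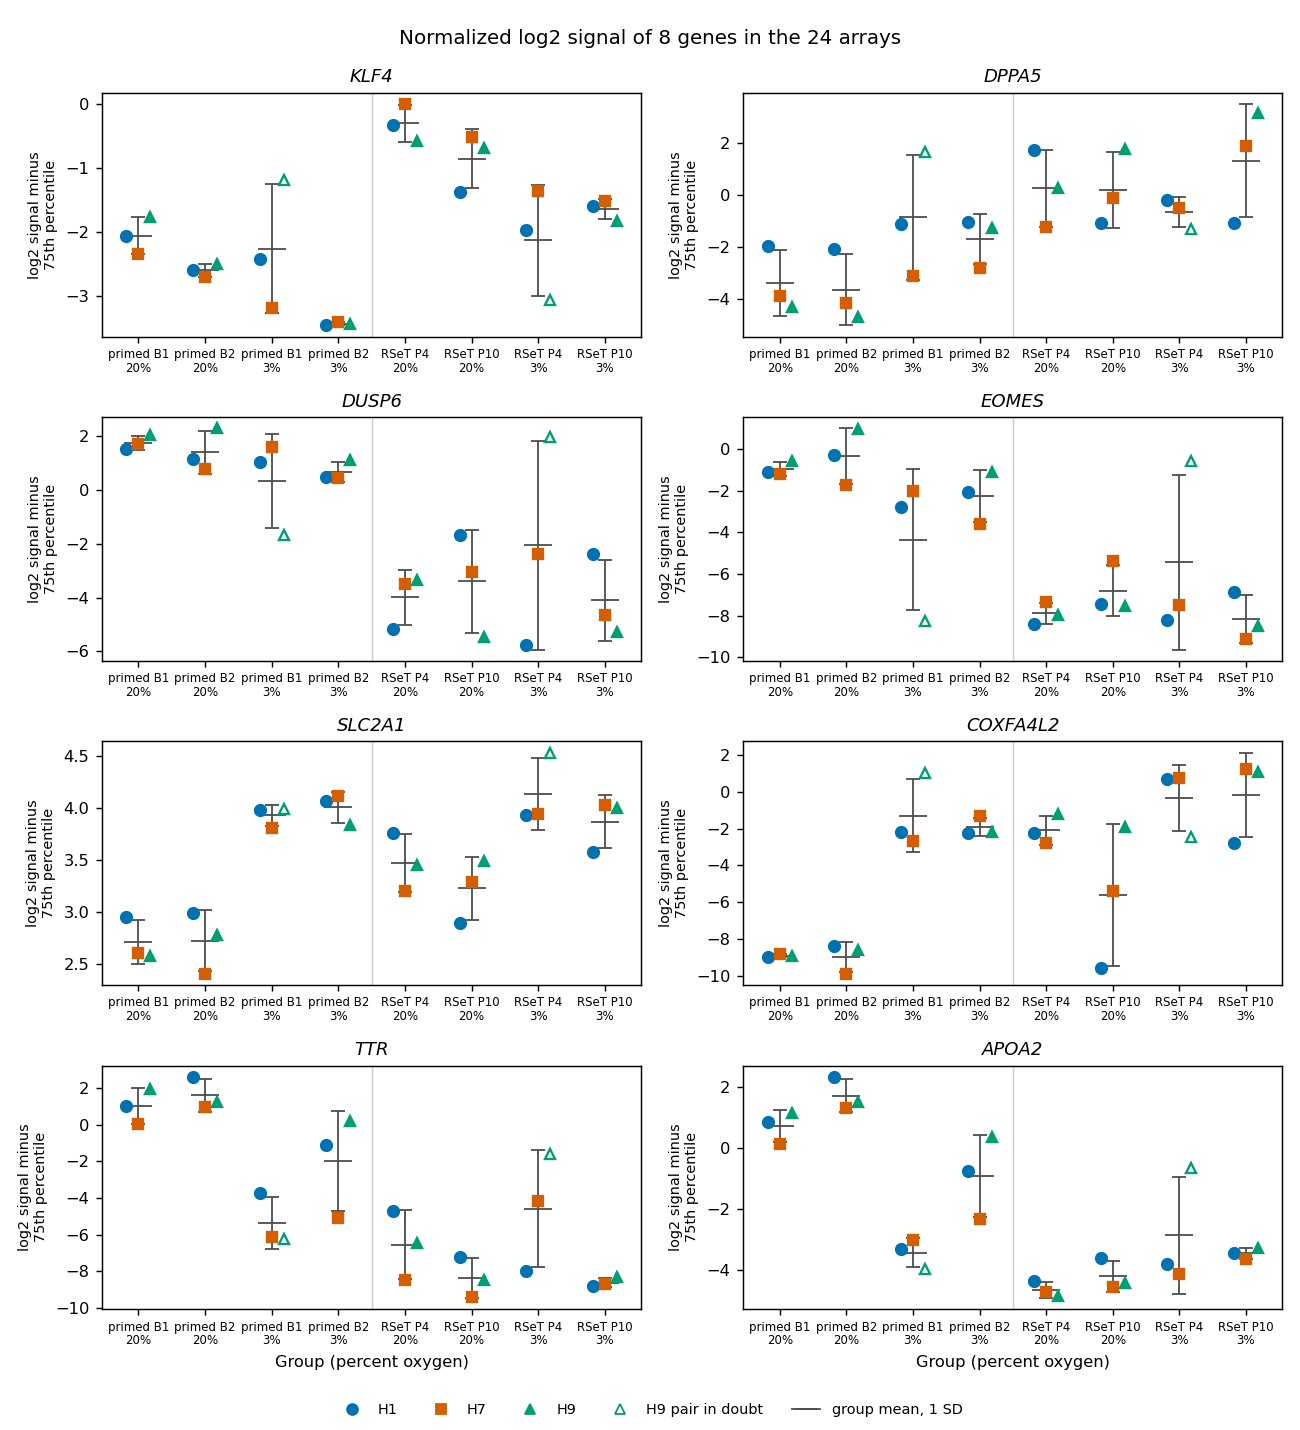
Scaled log2 signal of KLF4, DPPA5, DUSP6, EOMES, SLC2A1, COXFA4L2, TTR and APOA2 in the 8 groups, 1 point per array coloured by line, with the group mean ± 1 SD (n = 3). Open triangles mark the pair of H9 arrays in doubt, and KLF4 lay 1.36 log2 units higher in RSeT than in primed cells while DUSP6 lay 4.43 lower.

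At 20% oxygen (n = 6 and 6) the media differed in these groups too. Camera called the fibroblast (median -0.74), primitive streak and mesoderm (-0.72) and trophectoderm and amnion lists (-0.38) lower, though not with an estimated correlation. KLF4 was higher in RSeT by 1.76 ± 0.30, DPPA5 by 3.73 ± 0.81, DNMT3L by 2.29 ± 0.54 and DPPA3 by 1.73 ± 0.35 (well above background on 3 RSeT and 2 primed arrays). ZNF560, not well above background on any primed array, was at least 18.5-fold higher by its own bound (adjusted p = 1.62e-05 by limma). With the common floor it was 1.82 log2 units higher and still called. TTR fell by 8.76 ± 0.89 (1 RSeT and 6 primed arrays; 6.24 with the common floor), APOA1 by 7.03 ± 0.60 (3 and 6), APOA2 by 5.66 ± 0.46, and the endoderm factor GATA6 by 6.27 ± 0.85 (4 and 6). Endoderm genes had 16 lower and 0 higher of 23, also when adjusted over the list alone. Their median was -1.79, or -1.03 with 4 members at their bound (adjusted p = 2.89e-12, adjusted p = 0.0512 with an estimated correlation), and -1.49 and -2.09 within the scans. Naive genes had 12 higher and 3 lower of 22 (12 and 4 adjusted over the list alone). Their median was 1.09 (adjusted p = 0.00972, adjusted p = 0.492 with an estimated correlation), and 0.96 and 1.40 within the scans. The naive median was 0.70 with the common floor, where DPPA3 was not called. FGF-ERK response genes had 9 lower and 0 higher of 19 (12 lower adjusted over the list alone; median -1.53, adjusted p = 9.7e-06, adjusted p = 0.376 with an estimated correlation), and DUSP6 fell by 5.27 ± 1.01.

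Several genes of the hypoxia response were higher in RSeT than in primed cells while both were at 20% oxygen. COXFA4L2, a mitochondrial target of hypoxia-inducible factor (formerly NDUFA4L2), was at least 11.3-fold higher (adjusted p = 0.00211), with 5 RSeT arrays and no primed array well above background, but was not called with the common floor. FAM162A rose by 1.28 ± 0.25, the collagen hydroxylase P4HA2 by 1.54 ± 0.28, the pyruvate dehydrogenase kinase PDK1 by 0.98 ± 0.18, and the glucose transporter SLC2A1 by 0.63 ± 0.16. EPAS1, which encodes a hypoxia-inducible factor subunit, fell by 1.17 ± 0.29. COXFA4L2 and EPAS1 are not in the list of HIF targets. Its member ADM was lower in RSeT, with a scaled signal of 1.54 to 3.05 against 3.92 to 5.10 in primed cells. Of 33 HIF targets 14 were higher and 3 lower (16 and 3 adjusted over the list alone). Their median was 0.72 (adjusted p = 0.00169, adjusted p = 0.492 with an estimated correlation), and 0.98 and 0.38 within the scans. The H1 arrays of scan 2 ran the other way, with 6 of 33 targets higher in RSeT and a median of -0.68, against 0.66 to 1.12 in the other 5 pairs of arrays. Glycolysis genes, with TPI1 up by 0.61 ± 0.12, had 12 higher and 1 lower of 20 (15 and 1 adjusted over the list alone). Their median was 0.50 (adjusted p = 8.3e-05, adjusted p = 0.376 with an estimated correlation), and 0.77 and 0.36 within the scans. In all 2793 genes were higher and 2172 lower. Without the H9 pair, whose arrays enter only the spread here, 4454 were higher and 3726 lower. Scan 1 alone gave 3061 called genes, scan 2 alone 827 and normexp 2469.

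At 3% oxygen (n = 6 and 6) fewer genes were called, and the H9 pair lay in this comparison. SUSD2 was higher in RSeT by 1.44 ± 0.26, DNMT3L by 2.11 ± 0.54 (adjusted p = 0.0449), ZNF560 by 3.41 ± 0.65 (well above background on 5 RSeT and 2 primed arrays) and CD3G by 3.51 ± 0.64 (5 and 2). DPPA3, not well above background on any primed array, was at least 1.13-fold higher (3 RSeT arrays; adjusted p = 0.0404). MYC fell by 1.99 ± 0.49, TAGLN by 3.21 ± 0.53, the natriuretic peptide gene NPPB by 3.08 ± 0.46, CCN2 by 1.37 ± 0.21, MYL7 by 3.80 ± 0.98 and GASK1B by 3.82 ± 0.76 (1 and 5 arrays). Of these DNMT3L, CD3G, DPPA3, MYC, MYL7 and GASK1B were not called with the common floor. KLF4 (0.96 ± 0.30, adjusted p = 0.0835), DPPA5 (1.59 ± 0.81, adjusted p = 0.273) and DUSP6 (-3.59 ± 1.01, adjusted p = 0.0596) did not pass, and without the pair all 3 were called, at 1.47, 2.38 and -5.09. Within H9 alone KLF4 differed by -0.13 and MYL7 by -0.24, against 1.16 and -5.71 in H1 and 1.87 and -5.46 in H7.

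FGF-ERK response genes had 1 lower and 0 higher of 19 at 3% oxygen, but 16 lower adjusted over the list alone (median -1.13, adjusted p = 7.32e-10, adjusted p = 0.281 with an estimated correlation; -0.84 in scan 1, -1.93 there without the pair, and -1.62 in scan 2). Activin-NODAL genes had 1 lower of 13 and 10 lower adjusted over the list alone (median -1.22, adjusted p = 6.99e-08, adjusted p = 0.281 with an estimated correlation; -1.11 in scan 1, -2.48 there without the pair, and -1.49 in scan 2). Naive genes had 3 higher and 0 lower of 22 (8 and 1 adjusted over the list alone). Their median was 0.87, or 0.63 with 2 members at their bound (adjusted p = 0.00658, adjusted p = 0.491 with an estimated correlation), 0.17 in scan 1, 0.74 there without the pair, and 1.62 in scan 2, or 0.47 with the common floor. Endoderm genes had 2 lower of 23 (1 higher and 11 lower adjusted over the list alone; median -0.79, or -0.63 with 1 member at its bound and 1 left out; adjusted p = 0.000146, adjusted p = 0.34 with an estimated correlation), but the median was 0.24 in scan 1, -0.56 there without the pair, and -1.43 in scan 2, or -0.31 with the common floor. HIF targets had 0 called of 33 by limma (median 0.12, adjusted p = 0.934; 0.19 in scan 1, 0.59 there without the pair, and 0.02 in scan 2), SLC2A1 among them (0.03 ± 0.16, adjusted p = 0.94). In all 475 genes were higher and 223 lower, against 4224 and 3364 without the pair, and under quantile normalization the calls split into 331 higher and 272 lower. Under the series matrix values the split was 194 and 144, and under normexp 55 and 31.

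Low oxygen was set against normal oxygen in primed cells (n = 6 and 6) to describe their hypoxia response. SLC2A1 rose by 1.25 ± 0.16 (adjusted p = 0.00014), LDHA, which makes lactate, by 1.49 ± 0.19, PGK1 by 1.24 ± 0.16, the lactate exporter SLC16A3 by 3.18 ± 0.57, the angiogenic factor VEGFA by 1.55 ± 0.31, PLOD2 by 1.74 ± 0.27 and FAM162A by 1.77 ± 0.25. COXFA4L2, not well above background on any normoxic array, was at least 54.2-fold higher by its own bound (adjusted p = 0.000195 by limma). With the common floor it was 3.37 log2 units higher and still called. CA9, a carbonic anhydrase induced by hypoxia, rose by 1.37 ± 0.43 (adjusted p = 0.036) but at 1.06 was not called without the H9 pair, nor with the common floor (1.09). EPAS1 fell by 1.98 ± 0.29, and HIF1A differed by 0.22 ± 0.15 (adjusted p = 0.35). Of 33 HIF targets 22 were higher and 0 lower (27 and 0 adjusted over the list alone). Their median was 1.16 (adjusted p = 1.97e-12, adjusted p = 0.168 with an estimated correlation), and 1.25 and 1.07 within the scans. Of 20 glycolysis genes, TPI1 (0.97 ± 0.12) among them, 14 were higher and 0 lower, also when adjusted over the list alone. Their median was 0.69 (adjusted p = 1.07e-10, adjusted p = 0.0961 with an estimated correlation), and 0.78 and 0.71 within the scans. Oxidative phosphorylation genes had 8 higher of 45 (14 higher and 1 lower adjusted over the list alone). Their median was 0.21 (adjusted p = 0.00633, adjusted p = 0.666 with an estimated correlation).

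Several genes of differentiating cells fell in primed cells at 3% oxygen. TTR was lower by 5.00 ± 0.89 (well above background on 4 hypoxic and 6 normoxic arrays), APOA2 by 3.39 ± 0.46, APOA1 by 3.82 ± 0.60 (5 and 6), AFP, the fetal serum protein, by 3.79 ± 0.68 (3 and 6), GATA4 by 2.40 ± 0.42 (5 and 6) and the fibrinogen gene FGB by 4.27 ± 0.40 (2 and 6). FGA, not well above background on any hypoxic array, was at least 4.03-fold lower. Endoderm genes had 12 lower and 0 higher of 23 (13 lower adjusted over the list alone). Their median was -0.80, or -0.75 with 1 member at its bound (adjusted p = 6.63e-09, adjusted p = 0.0961 with an estimated correlation), and -1.27 and -1.22 within the scans. AKR1B10, an aldo-keto reductase, fell by 4.28 ± 0.32 (3 and 6), the mesoderm genes HAND1 by 3.30 ± 0.42 (1 and 6) and KDR by 2.08 ± 0.34. With the common floor TTR was at -4.58, APOA1 at -3.61, AFP at -2.11, GATA4 at -1.78, FGB at -1.29, FGA at -0.59, AKR1B10 at -2.66 and HAND1 at -0.77, all still called. Primitive streak and mesoderm genes had 1 higher and 3 lower of 18 (1 and 5 adjusted over the list alone; median -0.47, adjusted p = 0.00792, adjusted p = 0.168 with an estimated correlation), and trophectoderm and amnion genes 4 lower of 21, also when adjusted over the list alone. The trophectoderm and amnion median was -0.39 (adjusted p = 0.0187, adjusted p = 0.261 with an estimated correlation). With the common floor it was -0.17 and not called (adjusted p = 0.0569), and the primitive streak median was -0.26.

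Some targets of WNT and BMP signalling fell beside them. The WNT targets TCF7 (1.01 ± 0.15 lower) and DKK1 (2.71 ± 0.65 lower) fell, and LGR5, not well above background on any hypoxic array, was at least 1.22-fold lower (4 normoxic arrays; adjusted p = 0.00272). LGR5 turned with the series matrix values (0.43, adjusted p = 0.39) and was not called with the common floor. WNT response genes had 6 lower and 0 higher of 20 (13 lower adjusted over the list alone). Their median was -0.91, or -0.79 with 1 member at its bound (adjusted p = 1.5e-05, adjusted p = 0.0961 with an estimated correlation), and -1.02 and -0.98 within the scans, or -0.58 with the common floor. ID3, induced by BMP, fell by 1.81 ± 0.38, among 4 lower and 0 higher of 15 BMP response genes (8 lower adjusted over the list alone). Their median was -1.11 (adjusted p = 9.2e-05, adjusted p = 0.271 with an estimated correlation), and -1.01 and -1.31 within the scans. POU5F1 rose by 0.72 ± 0.19 (adjusted p = 0.0153). The germ line genes MAEL (2.32 ± 0.63, 5 and 2 arrays) and PIWIL2 (2.56 ± 0.69) rose, 3 higher of 18, also when adjusted over the list alone. The germ line median was 0.79 (adjusted p = 0.0162, adjusted p = 0.666 with an estimated correlation). With the common floor it was 0.24 and without the pair 0.54, not called in either (adjusted p = 0.108 and 0.0649), and MAEL lost its call with the floor. VAV1, a signalling gene of blood cells, rose by 3.94 ± 0.45 (5 and 3). In all 2581 genes were higher and 1714 lower, against 3262 and 2721 without the pair, and quantile normalization gave 2144 and 2187. Scan 1 alone gave 1909 called genes, scan 2 alone 573 and normexp 1728.

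The oxygen response of RSeT cells (n = 6 and 6) had fewer calls. SLC2A1 rose by 0.65 ± 0.16 (adjusted p = 0.0286), LDHA by 0.84 ± 0.19, the glycolytic enzyme ENO1 by 0.60 ± 0.12, PLOD2 by 1.33 ± 0.27, the oxygen sensor EGLN3 by 0.92 ± 0.19, COXFA4L2 by 3.61 ± 0.97 (well above background on 6 hypoxic and 5 normoxic arrays; not called with the common floor) and VAV1 by 3.63 ± 0.45. VEGFA (1.04 ± 0.31, adjusted p = 0.0621) and CA9 (1.32 ± 0.43, adjusted p = 0.0803) did not pass, nor did EPAS1 (-0.34 ± 0.29, adjusted p = 0.507). Of 33 HIF targets 4 were higher and 0 lower (11 and 0 adjusted over the list alone). Their median was 0.66 (adjusted p = 1.06e-06, adjusted p = 0.501 with an estimated correlation), and 0.53 and 0.78 within the scans. Glycolysis genes had 7 higher and 0 lower of 20 (15 and 0 adjusted over the list alone). Their median was 0.47 (adjusted p = 1.06e-06, adjusted p = 0.501 with an estimated correlation), and 0.33 and 0.68 within the scans. KLF4 fell by 1.31 ± 0.30 (adjusted p = 0.0235), ID3 by 1.62 ± 0.38, ZIC5 by 1.64 ± 0.40, FOXD4 by 2.76 ± 0.27 (4 and 6 arrays), and the ERK feedback inhibitors SPRY2 by 1.35 ± 0.35 and SPRED2 by 1.49 ± 0.28 (5 and 6 arrays).

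FGF-ERK response genes had 2 lower and 0 higher of 19 in RSeT at 3% oxygen (7 lower adjusted over the list alone). Their median was -0.44 (adjusted p = 0.00137, adjusted p = 0.557 with an estimated correlation), -0.33 in scan 1, -1.36 there without the pair, and -0.69 in scan 2. In primed cells these genes had 3 lower and 0 higher, also when adjusted over the list alone. The primed median was -0.78 (adjusted p = 0.00514, adjusted p = 0.666 with an estimated correlation), -0.92 in scan 1, -0.46 there without the pair, and -0.48 in scan 2. The FGF-ERK median of the effect in RSeT minus that in primed cells was 0.03 (adjusted p = 0.901), and -0.55 without the pair (adjusted p = 0.0054, adjusted p = 0.521 with an estimated correlation; -0.87 in scan 1 and -0.14 in scan 2). BMP response genes had 1 lower of 15, also when adjusted over the list alone. Their median was -0.65, or -0.61 with 1 member at its bound (adjusted p = 0.00137, adjusted p = 0.501 with an estimated correlation), and -0.88 and -0.63 within the scans. Endoderm genes had 1 lower of 23 (2 higher and 1 lower adjusted over the list alone; median 0.23, adjusted p = 0.732) and naive genes 1 higher and 1 lower of 22 (median -0.26, adjusted p = 0.299). In all 862 genes were higher and 382 lower, against 1432 and 963 without the pair. Quantile normalization gave 683 and 500, and normexp 44 and 44.

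Whether oxygen acted differently in the 2 media was tested as an interaction, the effect in RSeT minus that in primed cells (4 sets of 6 arrays). APOA2, well above background on all 24 arrays, had an oxygen effect higher in RSeT than in primed cells by 4.67 ± 0.65. In this paragraph higher and lower refer to that difference of effects and not to the level, which for APOA2 was lower in RSeT (-3.32 over both oxygen levels). TTR (5.85 ± 1.25, adjusted p = 0.043; well above background on 3 of 12 RSeT arrays), APOA1 (4.205 ± 0.84; 5 arrays) and GATA4 (3.19 ± 0.60; 6 arrays) were also higher, but were dim in RSeT. Of 23 endoderm genes 6 were called higher and 0 lower (13 and 0 adjusted over the list alone). Their median was 1.39 (adjusted p = 2.87e-11, adjusted p = 0.0703 with an estimated correlation), 1.54 in scan 1, 1.08 there without the pair, and 0.98 in scan 2. In RSeT passage 4 at 3% oxygen the H9 array in doubt had APOA2 at -0.66, against -3.81 in H1 and -4.15 in H7. Without the 4 members not well above background on any RSeT array at 20% oxygen the median of the other 19 was 1.01. With the common floor this median was 0.38 and 4 members were called higher. TTR was then at 5.22, APOA1 at 4.07 and GATA4 at 1.94, all still called. Their RSeT group means at 20% oxygen lay below the floor, so a further fall in RSeT could not show. A fall in primed cells alone thus gives a higher value, and the floored calls cannot decide whether oxygen acted differently on them. AKR1B10 (4.38 ± 0.45, or 2.66 with this floor; 5 RSeT arrays) and MIXL1 (1.88 ± 0.39; 10 RSeT arrays) were also higher, and FOXD4 (-1.84 ± 0.38) and TIGD7 (-1.31 ± 0.19) lower. With this floor the AKR1B10 value equals the size of its fall in primed cells (-2.66), and the FOXD4 value (-1.84) equals its fall in RSeT (-1.84). Among HIF targets no gene was called: SLC2A1 differed by -0.60 ± 0.22 (adjusted p = 0.252) and FAM162A by -1.19 ± 0.35 (adjusted p = 0.141). EPAS1, which is not in that list, differed by 1.64 ± 0.41 (adjusted p = 0.0739) and was called without the H9 pair at 1.93. The HIF list as a whole had a smaller response in RSeT (0 called of 33 by limma; median -0.56, adjusted p = 0.00011, adjusted p = 0.697 with an estimated correlation; -0.82 in scan 1, -0.46 there without the pair, and -0.26 in scan 2). Glycolysis genes leaned the same way (median -0.23, adjusted p = 0.000394, adjusted p = 0.423 with an estimated correlation; -0.53 and -0.11 within the scans), and WNT response genes the other (3 higher adjusted over the list alone). The WNT median was 0.67 (adjusted p = 0.00247, adjusted p = 0.298 with an estimated correlation), and 0.63 and 0.93 within the scans, or 0.38 with the common floor. In all 117 genes were higher and 35 lower, against 553 and 448 without the pair. Normexp gave 2 called genes, a fit without the replicate block 41, scan 1 alone 66 and scan 2 alone 1.

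**Figure D3:**
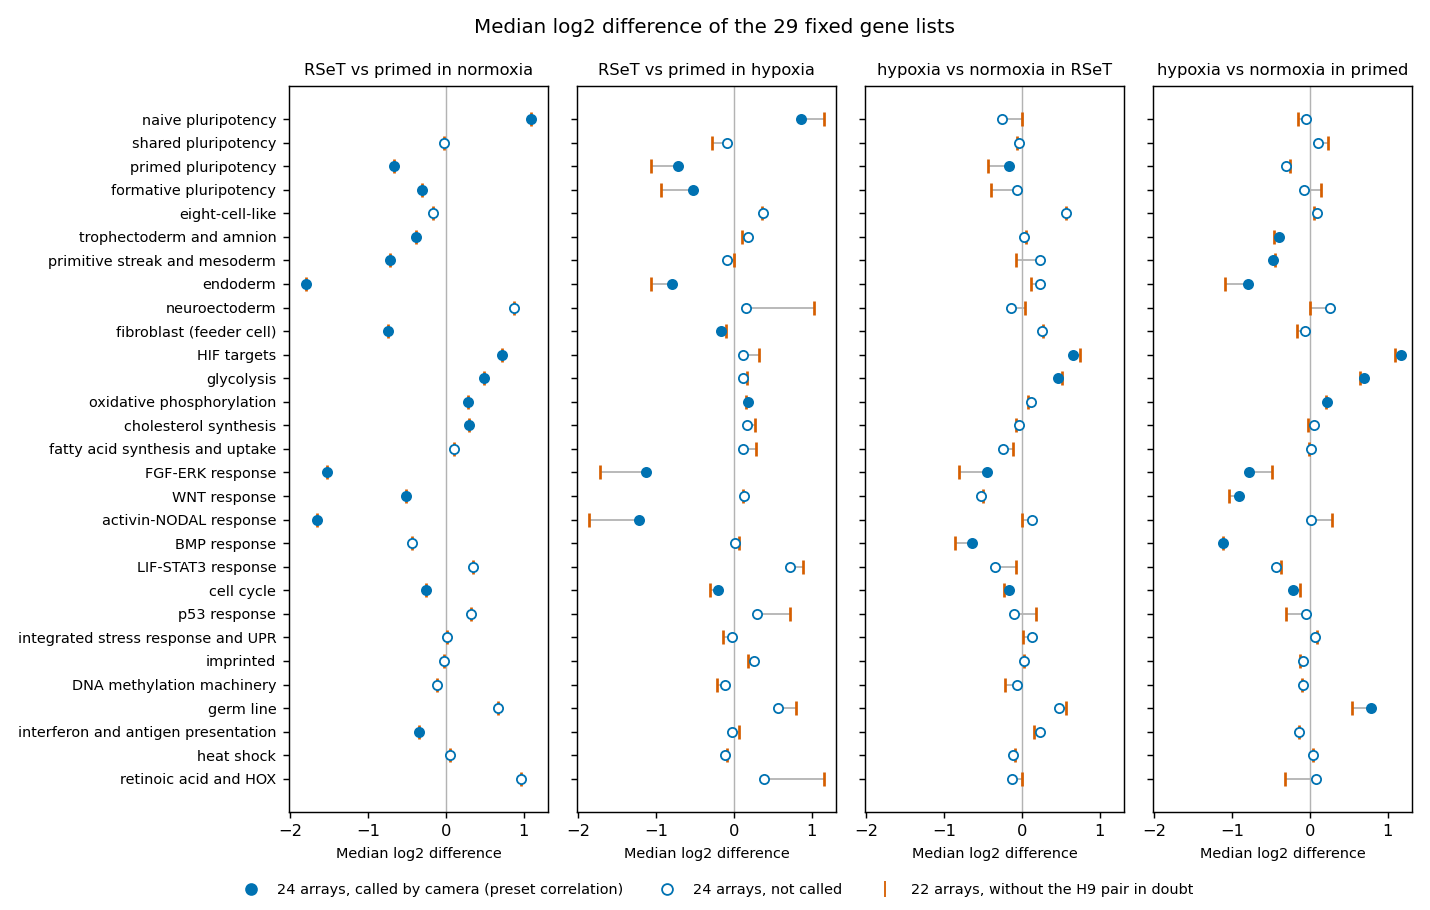
Median log2 difference of each of the 29 gene lists in 4 comparisons. Filled points are lists called by camera at a preset correlation and ticks give the median without the H9 pair in doubt. Endoderm genes lay at -0.80 in primed cells and 0.23 in RSeT cells at 3% against 20% oxygen.

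RSeT cells at passage 10 were set against passage 4 (n = 6 and 6), a comparison that lies between the scans, so passage and scan cannot be told apart. TFCP2L1, a naive transcription factor, was higher at passage 10 by 1.15 ± 0.25 (adjusted p = 0.0069), ZNF560 by 2.73 ± 0.65 (well above background on 6 and 5 arrays) and ZNF300P1 by 2.73 ± 0.54 (6 and 4). ADAM7, not well above background on any passage 4 array, was at least 1.64-fold higher. TGFB2 fell by 2.37 ± 0.43 (4 and 6), PDGFRB, a receptor of mesenchymal cells, by 2.06 ± 0.53 (5 and 6), COL5A1 by 1.297 ± 0.34, CRABP1 by 1.27 ± 0.27, SALL1 by 1.17 ± 0.27 and F2RL3 by 2.44 ± 0.34 (1 and 5). TTR, not well above background on any passage 10 array, was at least 3.25-fold lower (adjusted p = 0.0373) and was not called without the H9 pair. F2RL3 turned with normexp (0.12) and with the series matrix values (0.10). At the common floor ADAM7, TGFB2, PDGFRB, F2RL3, TTR and P4HA2 were not called. HIF targets had 4 lower and 0 higher of 33 (5 lower adjusted over the list alone), P4HA2 (0.87 ± 0.28 lower) and ANGPTL4 (1.58 ± 0.42 lower) among them. Their median was -0.38 (adjusted p = 1.2e-05 by camera, adjusted p = 0.686 with an estimated correlation). Glycolysis genes had 3 lower of 20, PGK1 (0.52 ± 0.16 lower) among them (median -0.32, adjusted p = 1.2e-05, adjusted p = 0.645 with an estimated correlation). Fibroblast genes had 3 lower of 23, or 5 adjusted over the list alone (median -0.37, adjusted p = 0.000695, adjusted p = 0.645 with an estimated correlation). The p53 response genes had 2 lower of 20, DDB2 (0.61 ± 0.17 lower) among them (median -0.39, adjusted p = 0.0057, adjusted p = 0.686 with an estimated correlation). Naive genes had 4 higher of 22 (median 0.37, adjusted p = 0.331).

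In all 2183 genes were higher and 1057 lower at passage 10, against 4479 and 2273 without the pair. The split moved with the scaling, to 1444 and 1368 with quantile normalization, 157 and 227 with normexp, 1307 and 1360 with a signal floor, 455 and 679 with the series matrix values and 2360 and 2479 without a filter on dim probes.

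Primed batch 2 was set against batch 1 (n = 6 and 6), likewise between the scans. SLC5A9, a sugar transporter gene, was higher in batch 2 by 2.53 ± 0.25 (adjusted p = 7.77e-05; 6 and 3 arrays), ADAM7 by 2.15 ± 0.28 (6 and 1), LUM by 2.87 ± 0.52 (6 and 3), APOA2 by 1.76 ± 0.46 and GATA4 by 1.56 ± 0.42 (6 and 5). CCL15, not well above background on any batch 1 array, was at least 1.71-fold higher. The neural genes DLX1 (1.72 ± 0.26 lower, 2 and 6 arrays) and INSM1 (1.37 ± 0.24 lower) fell, and F2RL3, not well above background on any batch 2 array, was at least 2.52-fold lower. With the series matrix values CCL15 (-0.68), DLX1 (0.19) and F2RL3 (0.19) turned. At the common floor SLC5A9, ADAM7, APOA2, CCL15, DLX1 and F2RL3 were not called. Endoderm genes had 3 higher and 0 lower of 23 (4 higher adjusted over the list alone). Their median was 0.36 (adjusted p = 0.137). Camera called 6 lists lower relative to other genes, with medians of -0.48 for LIF-STAT3 response, -0.20 for p53 response, -0.16 for cholesterol synthesis, -0.15 for HIF targets, -0.06 for stress response and -0.04 for cell cycle genes, though limma called 0 members of these lists (their adjusted p was 0.0373 to 0.0472, and 0.711 to 0.798 with an estimated correlation). With the common floor none of these lists was called (adjusted p = 0.0838 to 0.0875), and without the pair only cell cycle genes were (adjusted p = 0.00806). In all 1103 genes were higher and 112 lower, against 1900 and 445 without the pair, 24 and 1 with normexp, 653 and 199 with quantile normalization and 1345 and 1209 without a filter on dim probes.

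The passage difference minus the batch difference cancels a scan effect shared by both media. SLC5A9 (probe at chromosome 1, 48713661 to 48713720, hg19) was called lower (adjusted p = 0.000756), but 0 of 12 RSeT arrays were well above background. The call thus rests on the primed batches, and with the common floor it was lost (-0.52, adjusted p = 0.353). The other called probe, A_23_P407750 (chromosome 5, 101575078 to 101575137), has no gene name and was chosen after its values were seen; it was higher by 2.74 ± 0.37 (adjusted p = 0.0107), a call also lost with this floor (0.40, adjusted p = 0.413). TTR differed by -4.91 ± 1.25 (adjusted p = 0.195). Endoderm genes had 0 called of 23 by limma but 6 lower adjusted over the list alone (median -0.87, adjusted p = 1.76e-05, adjusted p = 0.347 with an estimated correlation), or -0.47 with this floor. Cholesterol synthesis genes leaned the other way (3 higher adjusted over the list alone). Their median was 0.37 (adjusted p = 0.000307, adjusted p = 0.365 with an estimated correlation). Only 1 gene was higher and 1 lower, against 104 and 103 without the H9 pair, and 2553 genes had an unadjusted p under 0.05. The passage and batch differences correlated across genes (Pearson 0.433, Spearman 0.424), and genes are not independent replicates.

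The lines differed in their response to the medium for 53 genes by a moderated F test (n = 4 and 4 arrays per line). H7 alone among the lines had higher FOXC1, a mesenchymal transcription factor, in RSeT (2.37, against -1.91 in H1 and -0.96 in H9; F 38.7, adjusted p = 0.0131). DIO3, a thyroid hormone deiodinase (1.59, against -3.37 and -2.67), and ZNF880 (2.85, against 0.10 and 0.32) also stood highest in H7. Without the H9 pair 765 genes were called, and with normexp 0. For the response to oxygen limma called 0 genes, with 436 at an unadjusted p under 0.05.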

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

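The tests of the H9 pair, the correlation with line means removed, the HIF medians by line and every count of exchanged labels in this part were chosen after the results were seen.

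The array labelled primed batch 1 hypoxia H9 carried an RSeT profile and the array labelled RSeT passage 4 hypoxia H9 a primed one, at RSeT scores of 1.07 and 0.0292. The biological explanation tested is that the RSeT culture alone had gone back to a primed profile. Its partner would then lie with the other primed arrays, but it lay 0.778 above the highest of them. Dim signal is argued against by the score of the array labelled RSeT over the brighter genes, -0.0371, where dimness would matter least. An exchange of labels or cultures within the pair may account for both values. On the slide each array lay where the other slides hold the medium of its profile. Position and profile thus go together, and only the label departs from both. An exchange of names alone would give this, whereas exchanged cultures would also need reversed positions. No other biological explanation was tested, and the exact step of an exchange stays open.

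Endoderm genes were lower in primed cells at 3% oxygen, with a median of -1.09 without the H9 pair. The dimmer hypoxia arrays are argued against: 0% of 10000 random lists of like size and brightness had a median as low (95% of them lay between -0.279 and 0.208), and 4 other scalings gave -1.10 to -0.63. Within groups of primed arrays the endoderm genes varied together (mean correlation 0.34 across 11 arrays, against a random median of 0.00401, with 0% of 1000 random lists as high), which is consistent with a changed share of endoderm-like cells in the cultures. With line means also removed the correlation was 0.16, reached by 0.1% of random lists, so line differences may hold part of it. Genes regulated together within every cell could give the same correlation, so regulation by oxygen within cells stays open. No count of cells by type was available.

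HIF targets were higher in RSeT than in primed cells at 20% oxygen, with a median of 0.72. Array scaling is argued against by the lowest median over 4 other scalings, 0.648. A difference of a single scan stays open. The lower of the within-scan medians was 0.384, in scan 2, but there the H1 arrays ran the other way (-0.68), so this value lies within the spread of the lines. RSeT cells at 20% oxygen may carry part of the response of primed cells to 3% oxygen, and the medium effect of each scan was set against the oxygen effect of the other across the 33 HIF targets, which are not independent replicates. The lower correlation was 0.411, but 29.3% of random lists reached it, and the higher was 0.495, reached by 11.6%. These cannot be told apart from the resemblance of both effects over all genes (r 0.287 and 0.275).

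The oxygen effect differed between the media for 152 genes, and 3 of 100 splits that exchanged labels within matched pairs of arrays gave as many (highest other 3799). Such splits exchange oxygen labels in either medium, so they can carry the oxygen effect shared by both media into this contrast. They therefore cannot decide whether chance could give 152 genes. Normexp called only 2 genes here. The oxygen effect also differed for 9 of the 29 gene lists by camera. That effect, not the level, was higher in RSeT than in primed cells for trophectoderm and amnion, primitive streak and mesoderm, endoderm, fibroblast, WNT response and interferon genes. It was lower for HIF targets, glycolysis and oxidative phosphorylation genes. With an estimated correlation 0 of these lists were called, and with a common signal floor the endoderm median went from 1.39 to 0.38. Passage and batch differences parted for 2 genes, and 8 of 100 splits gave as many (highest other 874). These splits can likewise carry a scan difference shared by both media into the contrast, so they cannot decide on chance, which is not excluded. Passage and batch differences also parted for 5 gene lists by camera, endoderm, fibroblast, HIF targets and glycolysis genes lower and cholesterol synthesis genes higher. With an estimated correlation 0 of these were called either, and the HIF result turned without H1 (median 0.07, adjusted p = 0.452). With a common signal floor 0 of the 2 genes were called. Lines differed in the medium effect for 53 genes, and 2 of 100 permutations of the line labels gave as many (highest other 116). The permutations also break up the line block, which moves the differences between lines into the spread of the permuted fits. They therefore cannot decide whether chance could give 53 genes.

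For the remaining counts, 1 split means that only the real labelling gave as many among the splits tried. The splits exchange arrays of the same line independently, though the 3 lines are the replicates. They therefore cannot exclude chance at the level of lines. For RSeT against primed only 100 splits were drawn, and the exchange of the H9 pair alone was not among them. RSeT against primed gave 6134 genes in 1 of 100 splits (highest other 5238), at 20% oxygen 4965 in 1 of 32 (highest other 1014). At 3% oxygen 5 of 32 splits gave as many as the 698 called (highest other 8175), so chance is not excluded, and that highest split exchanged only the H9 pair in doubt. Oxygen gave 1244 genes in RSeT in 1 of 32 splits (highest other 84) and 4295 in primed cells in 1 of 32 (highest other 96). Passage gave 3240 in 1 of 32 (highest other 1865) and batch 1215 in 1 of 32 (highest other 193). For the oxygen effect by line, 0 genes were called by limma and 436 had an unadjusted p under 0.05, and 100 of 100 permutations gave as many (highest other 3). With 0 called this share is fixed in advance, so it says nothing about chance.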

How the results depend on the processing

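The results without the H9 pair, with a common signal floor, and with the scans alone for the interactions were chosen after seeing the data. All counts are genes called by limma. In 154 called results of named genes the alternatives gave 6645 values, of which 5804 stayed called in the same direction, 835 kept the direction but were no longer called and 6 turned. Of 780 values for genes not called, 715 stayed so, 49 became called in the same direction and 16 took the other sign without a call. Signal over background limits genes dim on scan 1, whose lowest signal well above background was 15.8 to 21.99, against 7.27 to 10.9 on scan 2. The cause of a changed count was not tested unless given here.

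Background and scaling. With normexp, which raises the dim signals by an offset, 3613 genes were called between the media, 2469 at 20% and 86 at 3% oxygen, 88 for oxygen in RSeT and 1728 in primed cells, 2 for the oxygen by medium interaction, 384 for passage, 25 for batch, 0 for passage by batch and 0 for line by medium; it moved the median of all genes by 0.105 in passage by batch. Series matrix values gave 338 between the media at 3% oxygen, 3711 for oxygen in RSeT, 6878 in primed cells, 1134 for passage, 192 for batch, 13 for passage by batch and 2 for line by oxygen. A signal floor gave 656 for batch and 6 for passage by batch, a common signal floor 2083 for passage, 491 for batch and 10 for passage by batch (0 of them shared with the 2 called), and quantile normalization 30 for line by medium. Turned results were F2RL3 for passage (0.12 with normexp, 0.10 with series matrix values) and, with series matrix values, LGR5 for oxygen in primed cells (0.43), F2RL3 (0.19), DLX1 (0.19) and CCL15 (-0.68) for batch; the cause was not tested.

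Filters and fits. Without a filter on dim probes 90 genes were called for the oxygen by medium interaction and 2554 for batch. With probes well above background on 12 arrays these were 87 for the interaction and 1 for passage by batch, with fewer genes tested. Without the replicate block the counts were 2989 at 20% and 195 at 3% oxygen between the media, 333 for oxygen in RSeT, 2350 in primed cells, 41 for the interaction, 979 for passage, 276 for batch and 1 for passage by batch. Trend and robust eBayes gave 99 for the interaction, and the slide as block 34 for line by medium. With only the compared arrays, which lowers the degrees of freedom and drops the spread of the other arrays, 8220 were called at 20% and 0 at 3% oxygen between the media (4884 had an unadjusted p under 0.05 with all arrays), 252 for oxygen in RSeT and 2074 for passage.

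Stricter calls leave fewer genes by construction. At least 2-fold as well left 1462 genes between the media, 2033 at 20% and 315 at 3% oxygen, 409 for oxygen in RSeT, 1431 in primed cells, 1031 for passage and 516 for batch. An adjusted p under 0.01 left 3225, 2079 and 64 for the media, 176 for oxygen in RSeT and 1786 in primed cells, 32 for the interaction, 1006 for passage, 408 for batch, 1 for passage by batch and 1 for line by medium.

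Scans and the H9 pair. A scan alone limits the contrast to 1 scan, but the line terms and the spread come from the arrays of both scans. Only the line tests were refitted within a scan, so the other counts are not independent between scans. The H9 pair thus also enters the spread behind the scan 2 counts, the line tests aside. Scan 1 alone, with fewer arrays compared, gave 3029 between the media, 3061 at 20% and 0 at 3% oxygen. It gave 329 for oxygen in RSeT, 1909 in primed cells, 66 for the interaction and 0 for line by medium. Scan 2 alone gave 2874, 827 at 20% oxygen, 4 for oxygen in RSeT, 573 in primed cells, 1 for the interaction, 2088 for line by medium and 2 for line by oxygen. Without the H9 pair the counts were 10647 between the media, 8180 at 20% and 7588 at 3% oxygen, 2395 for oxygen in RSeT, 1001 for the interaction, 6752 for passage, 2345 for batch, 207 for passage by batch and 765 for line by medium. Of 82 list calls over 9 comparisons, 0 held with an estimated correlation and 41 by fry, which called 53 in all. With a common signal floor 71 lists were called, 69 of them as before, and without the pair 97, of which 71 as before and 0 with an estimated correlation.

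Leaving out a single array moved the count between the media from 4857 (without primed batch 1 hypoxia H1) to 9179 (without RSeT passage 4 hypoxia H9), a range written below as lowest to highest; the highest came without RSeT passage 4 hypoxia H9 unless another array is named. It was 3336 (RSeT passage 10 normoxia H9) to 7162 at 20% and 108 (primed batch 1 hypoxia H1) to 4382 at 3% oxygen, 317 (RSeT passage 4 normoxia H9) to 1867 (primed batch 1 hypoxia H9) for oxygen in RSeT, and 2652 (primed batch 1 normoxia H9) to 6168 in primed cells. For the interaction it was 66 (primed batch 1 normoxia H7) to 434, for passage 1895 (RSeT passage 10 normoxia H1) to 5617, for batch 649 (primed batch 2 normoxia H7) to 2412, for passage by batch 2 (RSeT passage 4 normoxia H1) to 57 (RSeT passage 10 hypoxia H7), for line by medium 2 (primed batch 1 normoxia H1) to 130, and for line by oxygen 0 throughout. Leaving out a whole line gave, without H7 and without H9, 1289 to 7430 between the media, 1125 to 3427 at 20% oxygen, 0 to 4824 at 3% oxygen (1 without H1), 0 to 331 for oxygen in RSeT and 1054 to 2182 in primed cells. It gave 2 (H1) to 12 (H9) for the interaction, 251 (H1) to 3721 (H9) for passage, 0 (H1) to 1403 (H9) for batch, 0 (H7) to 1 (H1) for passage by batch, 0 (H1) to 467 (H9) for line by medium and 0 for line by oxygen. The result for the list HIF targets in passage by batch difference turned without H1 (median 0.07; adjusted p = 0.000202 without H9 to 0.452 without H1; the cause was not tested).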

Other observations

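The gene groups below belong to the same comparisons. The without-pair values, the common signal floor and the RSeT scores were chosen after results were seen. No other test here was chosen after its result was seen. Some neural genes rose in RSeT without the list passing the test: HES5, a Notch target, rose by 1.97 ± 0.22 and DCX, a neuronal cytoskeletal gene, by 1.35 ± 0.15 (SE; n = 12 and 12), with 4 higher and 0 lower of 18 neuroectoderm genes, also when adjusted over the list alone (median 0.58, adjusted p = 0.122; median 0.84 and 9 higher and 1 lower without the H9 pair). Retinoic acid and HOX genes had 5 higher and 2 lower of 16, also when adjusted over the list alone (median 0.70, adjusted p = 0.0977). The retinol receptor STRA6 rose by 1.27 ± 0.24 and HOXB2 by 2.99 ± 0.88 (well above background on 11 RSeT and 7 primed arrays; 0.97 in H1, 6.36 in H7 and 1.65 in H9), while CYP26A1, which breaks down retinoic acid, fell by 1.94 ± 0.38. The fatty acid synthesis genes SREBF1 (1.32 ± 0.14) and ACACA (1.17 ± 0.20) rose and the fatty acid transporter CD36 fell by 3.18 ± 0.47 (2 and 11 arrays; not called with the common signal floor), with 4 higher and 3 lower of 20 (6 and 3 adjusted over the list alone; median 0.15, adjusted p = 0.556).

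Germ line genes had 7 higher and 1 lower of 18 (8 and 2 adjusted over the list alone; median 0.66, adjusted p = 0.122), TKTL1 among the higher (3.27 ± 0.94). Interferon and antigen presentation genes had 2 higher and 6 lower of 21 (2 and 7 adjusted over the list alone; median -0.11, adjusted p = 0.115), with the immunoproteasome gene PSMB8 lower by 1.12 ± 0.20 and HLA-B by 0.57 ± 0.12. LIF-STAT3 response genes had 5 higher and 2 lower of 15, also when adjusted over the list alone (median 0.54, adjusted p = 0.0977), and WNT response genes 4 higher and 6 lower of 20 (4 and 7 adjusted over the list alone; median -0.27, adjusted p = 0.107). BMP response genes had 0 higher and 2 lower of 15 (median -0.22, adjusted p = 0.125), p53 response genes 5 higher and 3 lower of 20 (median 0.35, adjusted p = 0.279), and eight-cell-like genes 1 higher of 8 (median 0.03, adjusted p = 0.905). Imprinted genes had 4 higher and 3 lower of 23 (median 0.00, adjusted p = 0.948), DNA methylation genes 2 higher and 1 lower of 14 (median -0.14, adjusted p = 0.395), stress response genes 2 higher and 2 lower of 23 (median -0.02, adjusted p = 0.665) and heat shock genes 1 higher and 2 lower of 14 (median 0.07, adjusted p = 0.612).

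The RSeT scores also differed among arrays whose labels and profiles match. The H1 arrays of RSeT passage 10 scored 0.63 and 0.79, the former the lowest of the other 11 RSeT arrays, and the H7 arrays of primed hypoxia scored 0.289 and 0.289, the highest of the other 11 primed arrays.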
